A study of Homo sapiens with 24 samples.

How the data were processed

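WM164 is an established human melanoma cell line with an activating BRAF mutation, and vemurafenib (also called PLX4032) is an inhibitor of mutant BRAF, the kinase upstream of MEK and ERK in the MAPK pathway. Per the labels' protocols, 200000 cells were seeded in each well of a 6-well plate, held in serum-free medium overnight and then given 3 uM vemurafenib or vehicle for 8 h. The medium during treatment was RPMI with 5% fetal bovine serum (FBS) or equal volumes of serum-free medium and cerebrospinal fluid (CSF) from 1 of 3 patients, here called CSF1, CSF2 and CSF3. The labels name 3 libraries for each of the 8 combinations of medium and drug, 24 in all. Each CSF came from 1 donor, so a difference between CSFs is a difference between 3 preparations. The labels do not say that the 3 libraries of a group came from separate experiments, so p-values measure only the spread between these libraries, which may be technical.

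Per the labels' protocols, 100 ng of RNA went into the Ovation Human FFPE RNA-seq system, which makes strand-specific libraries, and these were sequenced as paired 75-base reads on a NextSeq 500. Per the series design text, the authors mapped reads to hg19 with TopHat 2.0.13 and summed the raw count of reads per gene with HTSeq 0.6.1. The submitters' processing notes also name Bowtie2 2.2.3.0, the hs37d5 sequence and DESeq2 1.24.0, while the design text names DESeq2 1.6.3. The gene annotation, the HTSeq overlap mode and the strand setting are not given in the sources used here. Reads from near-identical paralogs, pseudogenes, overlapping genes and antisense genes may therefore have been assigned to another member, which concerns the metallothioneins, HSPA1A and HSPA1B, histones and ribosomal protein genes with their pseudogenes.

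The authors deposited a table of raw counts for 23369 gene symbols and a second table of normalized signal, in which each library's counts are divided by 1 size factor. Every deposited normalized signal equalled the count divided by the library's factor to within a relative deviation of 5.1e-15. Recomputed median-of-ratios factors matched the deposited ones to 0.0027 after 1 common factor of 1.029. The raw counts were used for every result. No row lacked a gene name. XIST and Y-linked symbols, 100 in number, were left out of all tests and CPM levels because the media carry donor material. The total counts given for the libraries and the recomputed median-of-ratios factors include them. Within a group the counts of any pair of libraries differed by more than sampling noise (chi-square per degree of freedom 2.88 to 26.3, lowest Pearson r 0.983 over genes), so every library was counted separately.

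Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, low-count genes were removed with filterByExpr over the 8 groups, which left 14162 genes, and 1 model with a mean for each of the 8 groups was fitted to all 24 libraries with the robust quasi-likelihood method. The removed genes held 0.045% of the counts. The fit had 16 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. There were 16 comparisons: vemurafenib against vehicle in each of 4 media, each CSF against FBS under vehicle and under vemurafenib, each pair of CSFs under vehicle, and the difference between the vemurafenib response in each CSF and that in FBS. Comparisons that use the same FBS libraries share their chance values. To describe this, 20 data sets with no change were simulated. All vehicle libraries, those of FBS included, were drawn from the mean of the FBS vehicle group with the fitted spread. Levels are CPM (counts scaled to a common library total after TMM), as mean ± SD over n = 3 libraries, and log2 differences carry the standard error (SE) of the fit.

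The design, the rule for the genes named, and 37 gene lists were fixed before the data were examined. Lists with at least 5 tested members, 32 in number, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 32 lists within each comparison, and again with a correlation estimated from the data. Which calls hold with the estimate is given beside each list. Counts of list members that rose or fell use the adjustment over all genes, and counts adjusted over the list alone are given beside them. Genes were named by rule: the 6 largest rises and 6 largest falls (3 and 3 for CSF against CSF and for CSF against FBS under vemurafenib) among called genes with a mean of at least 5 CPM in the higher group and, in 2-group comparisons, no overlap between replicates. To these were added up to 4 members of each called list and, always, DUSP6, SPRY4, ETV4, ETV5, CCND1, EGR1, FOS and MYC. Clone-based and locus-only symbols were not ranked.

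The size of the vemurafenib response in a CSF relative to FBS was the mean log2 change there divided by that in FBS, over genes called in the same direction in the other 2 CSFs. Gene positions and transcript lengths came from GENCODE release 44 lifted to GRCh37, the assembly also called hg19, and 21501 of the 23369 symbols matched it. Alternatives planned from the start were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 Wald test, the replicate number as a block, only the libraries compared, and each library left out in turn. A correction of each library for transcript length and GC trends, alone or with the block, and the relative size over MAPK list members only were added after the data had been seen. The procedure was tested on simulated data made from the real libraries with 200 changed genes. For vemurafenib against vehicle in FBS it called 47.8% of genes changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 95.5% of those changed by 2, among 13919 genes. For the CSF3 response difference the shares were 19.4%, 76.1% and 87.9% among 13907 genes, so small differences between responses can often be missed. Most real comparisons called many more genes than were simulated as changed, which makes the adjusted threshold less strict. These shares are therefore not those of the real tests.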

Results

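RNA was sequenced from WM164 melanoma cells after 8 h with 3 uM vemurafenib or vehicle in medium with 5% FBS or in medium mixed with the CSF of 1 of 3 patients. The 24 libraries formed 8 groups of 3. Their total counts ranged from 9304026 in CSF1 vemurafenib 1 to 49516883 in FBS vemurafenib 2, with a median of 14195999. The first principal component of log2 CPM held 45.8% of the variance and separated all 12 vemurafenib libraries from all 12 vehicle libraries.

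The first question was how the cells responded to vemurafenib in each medium. Transcripts that report MAPK signalling fell in all 4. DUSP6, a phosphatase that inactivates ERK (GRCh37 chromosome 12, 89741012 to 89746278), went from 151 ± 3.77 to 1.66 ± 0.760 CPM (SD, n = 3) in FBS, and from 333 ± 8.17 to 17.9 ± 1.90 CPM in CSF3. Its log2 change was -6.65 ± 0.15 (SE) in FBS, -6.36 ± 0.15 in CSF1, -6.16 ± 0.14 in CSF2 and -4.22 ± 0.12 in CSF3, with edgeR adjusted p between 7.16e-24 and 6.32e-21. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling (chromosome 5, 141689992 to 141706020), changed by -4.96 on the log2 scale in FBS, -4.40 in CSF1, -4.28 in CSF2 and -2.67 in CSF3. The ETS factor ETV5 (chromosome 3, 185764103 to 185828107) changed by -3.17 ± 0.09, -3.14 ± 0.09, -3.32 ± 0.09 and -1.74 ± 0.09 in the same order. For MYC (chromosome 8, 128747680 to 128755197) the changes were -2.27 ± 0.11, -1.87 ± 0.10, -1.76 ± 0.10 and -0.87 ± 0.10. Cyclin D1, CCND1 (chromosome 11, 69455924 to 69469242), fell from 1995 ± 242 to 221 ± 6.70 CPM in FBS and from 1555 ± 48.5 to 297 ± 5.28 CPM in CSF3.

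Of the 19 tested members of the MAPK pathway output list, 18 fell and 0 rose in each medium, also when adjusted over the list alone. Its median log2 change was -2.27 in FBS, -2.42 in CSF1, -2.33 in CSF2 and -1.61 in CSF3, with camera adjusted p from 2.97e-29 to 9.18e-23, and all 4 calls held with an estimated correlation (adjusted p at most 1.07e-05). EGR1, an immediate early transcription factor outside that list (chromosome 5, 137801168 to 137804992), changed by -3.28 on the log2 scale in FBS, -4.09 in CSF1, -5.13 in CSF2 and -5.69 in CSF3. Its vemurafenib level was 32.8 ± 11.5 CPM in FBS and 9.32 ± 2.87 CPM in CSF3. FOS did not follow it: its log2 change was 0.08 ± 0.14 in FBS (adjusted p = 0.67 in edgeR) and -0.04 ± 0.14 in CSF2 (adjusted p = 0.86). In CSF1 it was called at 0.36 ± 0.14, but lost the call without CSF1 vehicle 3, CSF1 vemurafenib 2 or CSF1 vemurafenib 3, with adjusted p up to 0.211. In CSF3 it was called at 0.41 ± 0.14 and lost the call without CSF3 vehicle 2 or 3 or CSF3 vemurafenib 2 or 3, with adjusted p up to 0.112.

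**Figure D1:**
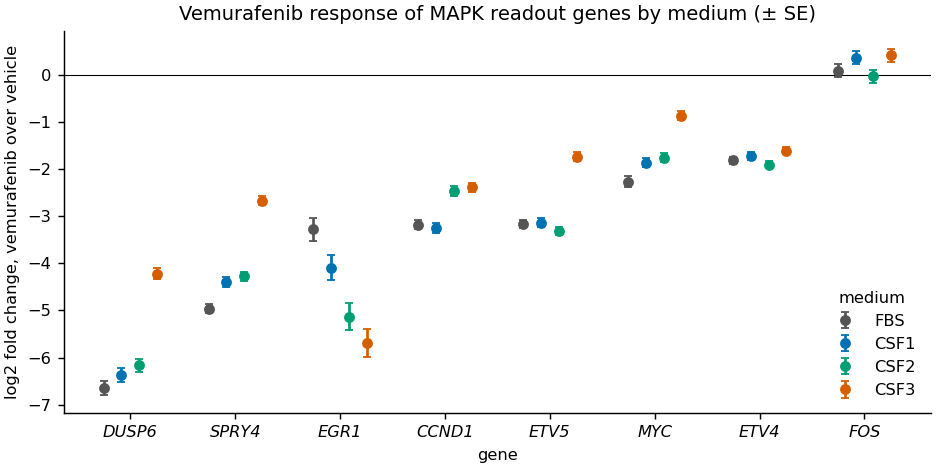
Log2 change under vemurafenib against vehicle (vertical axis) of 8 MAPK readout genes in each medium; points are edgeR estimates and bars their SE, from 3 libraries per group. DUSP6 lay at -6.65 in FBS and -4.22 in CSF3, while EGR1 lay at -3.28 in FBS and -5.69 in CSF3.

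Other changes were shared by all 4 media. Genes of the G1/S transition and DNA replication fell together: 20 of 22 in FBS and 21 of 22 in each CSF, or 21 in each medium when adjusted over the list alone. Their median log2 change was between -0.91 and -0.72, the camera adjusted p was at most 2.35e-11, and at most 0.00789 with an estimated correlation. CDC25A, which activates cyclin-dependent kinases, fell by 1.95 on the log2 scale in FBS, and the replication factor MCM10 fell by 1.59 there and by 1.64 in CSF1. Ribosome biogenesis genes fell as well, 22 of 22 in FBS, 21 in CSF1, 18 in CSF2 and 21 in CSF3 (22, 21, 19 and 22 adjusted over the list alone), with medians of -1.21, -0.99, -0.75 and -0.84. These 4 calls had a camera adjusted p of at most 6.70e-12, and of at most 0.000882 with an estimated correlation. The nucleolar protein NOLC1 changed by -1.35 ± 0.06 in FBS and -1.01 ± 0.06 in CSF3.

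Genes induced by FOXO factors when PI3K signalling is low rose: 10 of 16 in FBS, 13 in CSF1, 12 in CSF2 and 13 in CSF3, with none falling (10, 13, 13 and 13 adjusted over the list alone). The camera adjusted p was at most 1.34e-05, and at most 0.00285 with an estimated correlation. In FBS cyclin G2, CCNG2, rose by 1.82 ± 0.13 (log2) and the insulin receptor substrate IRS2 by 0.92 ± 0.07. Among 22 melanocyte differentiation genes 12 rose and 2 fell in FBS, 11 rose and 3 fell in CSF1, 13 rose and 6 fell in CSF2, and 14 rose and 2 fell in CSF3, the same counts as adjusted over the list alone. This list was called upward by camera in each medium (adjusted p from 2.58e-06 to 0.00424). With an estimated correlation the call was lost in CSF2 (adjusted p = 0.0708 with an estimated correlation) and held in the others. The endothelin receptor EDNRB rose by 1.79 ± 0.09 in FBS and 1.54 ± 0.09 in CSF3, and DCT, an enzyme of melanin synthesis, by 1.28 ± 0.08 and 1.07 ± 0.08.

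Large rises and falls of single genes included those of TGFB2, CEBPD, KCNJ13, LIF and UCN2. TGFB2, a secreted growth factor (chromosome 1, 218518678 to 218617961), went from 2.27 ± 0.396 to 17.6 ± 1.86 CPM in FBS and rose by 2.99 ± 0.18, 2.86 ± 0.16, 2.48 ± 0.16 and 2.26 ± 0.19 (log2) in FBS, CSF1, CSF2 and CSF3. The transcription factor CEBPD (chromosome 8, 48649475 to 48650726) rose by 3.17 ± 0.10 in CSF1, 2.60 ± 0.09 in CSF2 and 2.43 ± 0.09 in CSF3, and the edgeR adjusted p was at most 1.51e-18. KCNJ13, a potassium channel gene, was almost absent under vehicle in FBS (0.0525 ± 0.0494 CPM, with no more than a few reads per library) and reached 7.12 ± 0.183 CPM under vemurafenib there, against 2.00 ± 0.408 CPM in CSF3. The cytokine LIF (chromosome 22, 30636442 to 30642748) fell from 217 ± 24.3 to 9.49 ± 3.22 CPM in FBS, and its log2 change lay between -5.10 and -4.57 over the media. UCN2, a peptide hormone of the corticotropin-releasing family, changed by -5.08 ± 0.23 in FBS and -4.83 ± 0.27 in CSF3.

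Cholesterol synthesis and uptake genes fell under vemurafenib in CSF1, where 18 of 23 fell and 1 rose (18 and 2 adjusted over the list alone), and in CSF2, where 16 fell and 1 rose, also when adjusted over the list alone. The camera adjusted p was 6.95e-08 and 3.75e-08, or 0.00689 and 0.00749 with an estimated correlation. SQLE, which encodes squalene epoxidase, changed by -1.05 ± 0.08 in CSF1 and -0.99 ± 0.08 in CSF2. The list was not called in FBS or CSF3. Mitotic genes of the G2/M list rose in CSF1 and CSF2, 15 of 22 in each with none falling (16 in each adjusted over the list alone), with camera adjusted p of 2.17e-05 and 6.54e-05. Those calls were lost with the estimate (adjusted p = 0.0952 and 0.095 with an estimated correlation). KIF20A, a mitotic kinesin, rose by 1.16 ± 0.08 and 0.83 ± 0.08. Heat shock genes fell in all 4 media, 10 of 12 in FBS, 8 in CSF1, 9 in CSF2 and 7 in CSF3, with camera adjusted p from 0.000134 to 0.00895, and no call held (adjusted p from 0.0903 to 0.205 with an estimated correlation). Adjusted over the list alone, 10, 8, 9 and 8 fell. Immediate early genes fell in each medium too, 9, 8, 10 and 7 of 15 (9, 11, 10 and 8 adjusted over the list alone), with camera adjusted p at most 0.000154 and adjusted p from 0.0708 to 0.119 with an estimated correlation.

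In total 7313 of 14162 genes were called in FBS (3653 higher, 3660 lower), 6055 in CSF1 (3021 and 3034), 5657 in CSF2 (2693 and 2964) and 4964 in CSF3 (2366 and 2598). No single library left out moved any of these 4 counts by more than 1.5 times. In all 4 media 1126 genes were called higher and 1399 lower. FBS and CSF3 shared 1819 higher and 1986 lower genes, where independent lists of these sizes would share 610 and 671, and 25 genes were called in opposite directions. FBS and CSF2 shared 1581 higher and 1879 lower genes, against 695 and 766, with 229 in opposite directions, and FBS and CSF1 shared 2373 and 2331, against 779 and 784, with 22. The correlation of the log2 changes over genes with those in FBS was 0.804 for CSF1, 0.630 for CSF2 and 0.755 for CSF3. Each medium had its own vehicle libraries, so these lists share no controls. The list test called 11, 13, 15 and 13 of 32 lists in FBS, CSF1, CSF2 and CSF3, of which 6, 7, 5 and 5 held with an estimated correlation.

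**Figure D2:**
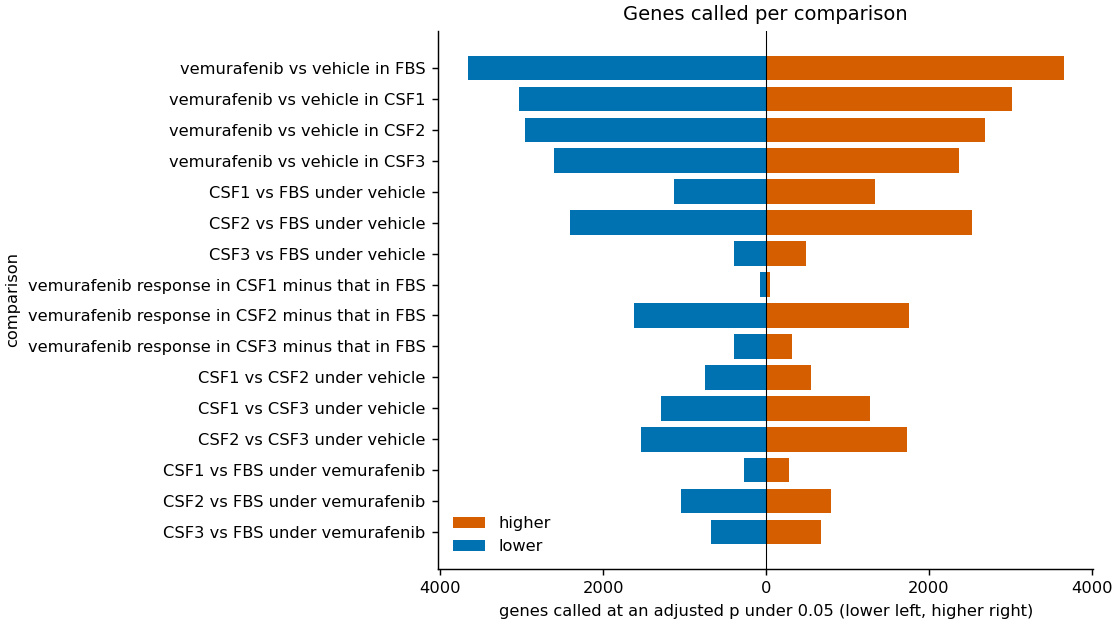
Number of genes called lower (left) and higher (right) at an edgeR adjusted p under 0.05 in each comparison, of 14162 genes tested. Vemurafenib against vehicle gave the largest counts, 7313 genes in FBS and 4964 in CSF3.

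The second question was how CSF differed from FBS under vehicle. The CSF media also lacked serum and held less of the basal medium, and no group had serum-free medium without CSF. In every comparison of CSF with FBS, effects of CSF therefore cannot be told apart from those of serum loss or dilution. Sterol genes moved in opposite directions in different CSFs. Of 23 cholesterol synthesis and uptake genes, 21 were higher in CSF1 than in FBS (median log2 difference 0.95) and 19 in CSF2 (median 0.58) with none lower, while 12 were lower in CSF3 (median -0.45) with none higher, and the counts were the same adjusted over the list alone. The camera adjusted p was 5.32e-26, 8.31e-13 and 1.11e-13, and 4.08e-05, 0.00274 and 0.00165 with an estimated correlation. HMGCS1, which makes the precursor of mevalonate (chromosome 5, 43287572 to 43313614), was at 49.8 ± 7.94 CPM in FBS, 158 ± 18.4 in CSF1, 124 ± 15.4 in CSF2 and 23.0 ± 1.93 in CSF3. INSIG1, a sterol-regulated membrane protein (chromosome 7, 155089486 to 155101945), differed from FBS by 1.53 ± 0.10, 1.16 ± 0.10 and -1.04 ± 0.10 (log2), with edgeR adjusted p of at most 4.65e-08. Of 11 fatty acid synthesis genes 5 were higher in CSF1 and 5 in CSF2 with none lower, and 6 were lower in CSF3 with none higher (6, 5 and 7 adjusted over the list alone). These calls had camera adjusted p of 0.00692, 0.00829 and 3.34e-06, and held in CSF3 (adjusted p = 0.0074 with an estimated correlation) but not in CSF1 or CSF2 (adjusted p = 0.0748 and 0.0843 with an estimated correlation).

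**Figure D3:**
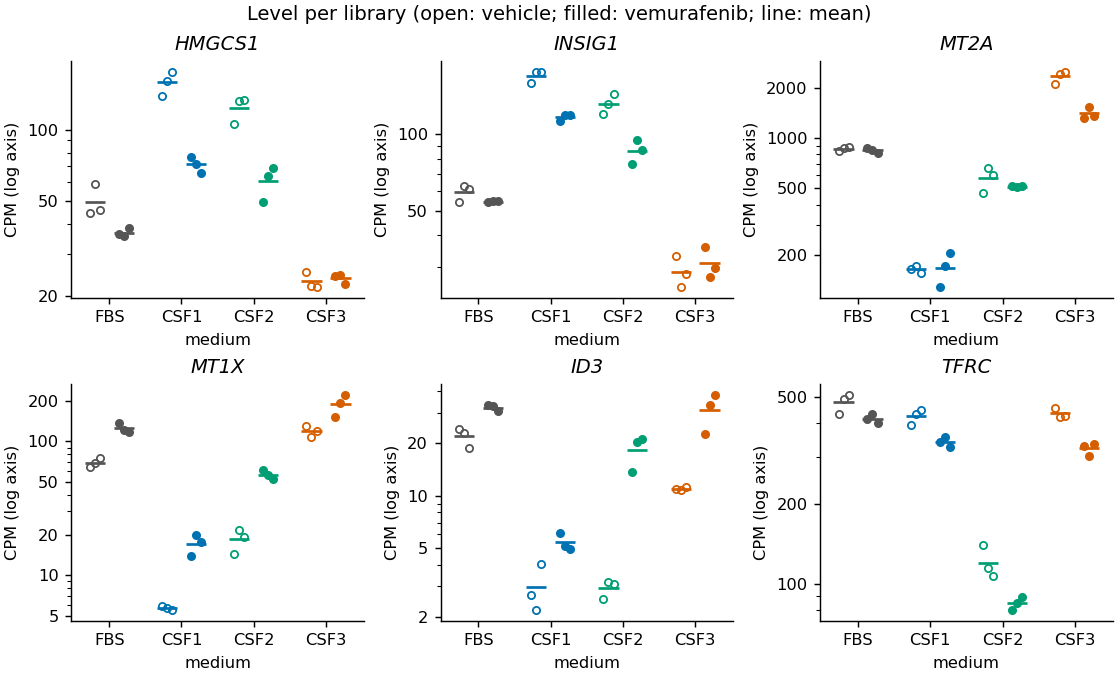
CPM (log axis) of 6 genes that differed between media, by medium; open points are vehicle libraries, filled points vemurafenib libraries and lines the means of 3 libraries. Mean HMGCS1 under vehicle was 158 CPM in CSF1, 124 in CSF2, 49.8 in FBS and 23.0 in CSF3.

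Single genes of metal handling differed too, although only 4 of the 8 members of the metallothionein and zinc list were tested, too few for a list test. The metallothionein MT1X (chromosome 16, 56716382 to 56718108) was at 69.5 ± 4.94 CPM in FBS, 5.69 ± 0.193 in CSF1, 18.6 ± 3.73 in CSF2 and 120 ± 11.4 in CSF3. MT2A (chromosome 16, 56642496 to 56643409) was 2.40 ± 0.12 lower (log2) in CSF1 and 1.44 ± 0.12 higher in CSF3 than in FBS. Metallothionein genes resemble one another, so their reads may have been shared in counting. The zinc exporter gene SLC30A1 (chromosome 1, 211744910 to 211752503) differed by -1.92 ± 0.17 in CSF1 and -1.80 ± 0.17 in CSF2. The transferrin receptor TFRC, which takes up iron (chromosome 3, 195739382 to 195809024), was at 120 ± 17.1 CPM in CSF2 against 479 ± 40.7 in FBS and 424 ± 28.0 in CSF1, a log2 difference of -2.00 ± 0.09 from FBS (edgeR adjusted p = 6.66e-16). ID3, a target of BMP signalling (chromosome 1, 23884417 to 23885992), was lower in all 3 CSFs, by -2.94 ± 0.20 in CSF1 and -2.90 ± 0.20 in CSF2, and at 11.0 ± 0.224 CPM in CSF3 against 22.0 ± 2.82 in FBS. CD200, a membrane glycoprotein (chromosome 3, 112051194 to 112081659), was higher by 2.14 ± 0.22 in CSF1 and 2.23 ± 0.22 in CSF2.

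Cell cycle genes were lower in CSF1 and CSF2 than in FBS. Of the 22 G1/S genes 16 were lower in CSF1 and 18 in CSF2 with none higher. Adjusted over the list alone, 18 were lower and 1 higher in CSF1, and 18 lower in CSF2. The camera adjusted p was 3.50e-12 and 9.49e-14, and 0.00976 and 0.00586 with an estimated correlation. Of the 22 G2/M genes 19 were lower in CSF1 and 13 in CSF2 (20 and 15 adjusted over the list alone), which held in CSF1 (adjusted p = 0.00976 with an estimated correlation) and not in CSF2 (camera adjusted p = 6.15e-06, adjusted p = 0.0843 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was lower by -0.64 ± 0.08 in CSF1 and -0.79 ± 0.08 in CSF2, and cyclin A2, CCNA2, by -0.64 ± 0.08 and -0.57 ± 0.08. Amino acid response genes controlled by ATF4 were higher in all 3 CSFs, 7 of 20 in CSF1, 7 in CSF2 (with 1 lower) and 6 in CSF3 (8, 9 and 9 adjusted over the list alone), and the call held in CSF3 (camera adjusted p = 9.11e-08, adjusted p = 0.0154 with an estimated correlation). It did not hold in CSF1 (0.000425, adjusted p = 0.0748 with an estimated correlation) or CSF2 (0.0122, adjusted p = 0.191 with an estimated correlation). TRIB3, a pseudokinase induced by this pathway, was higher by 1.51 ± 0.12, 0.85 ± 0.12 and 0.63 ± 0.12. Under vehicle DUSP6 was higher than in FBS by 0.56 ± 0.10 in CSF1, 0.48 ± 0.10 in CSF2 and 1.14 ± 0.10 in CSF3, and SPRY4 by 0.56 ± 0.08 in CSF2 and 0.64 ± 0.08 in CSF3, while in CSF1 SPRY4 was not called (0.18 ± 0.08, edgeR adjusted p = 0.141). In CSF1 6 of the 19 MAPK list genes were higher and 2 lower (7 and 3 adjusted over the list alone), with a camera adjusted p of 0.016 that was lost without FBS vehicle 3 (0.0545) and with the estimate (adjusted p = 0.109 with an estimated correlation), and in CSF2 5 were higher and 4 lower, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.397). In CSF3 6 of the 19 MAPK list genes were higher and 1 lower (7 and 2 adjusted over the list alone), with a camera adjusted p of 0.00294 that was lost (adjusted p = 0.0749 with an estimated correlation).

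Against FBS under vehicle 2469 genes were called in CSF1 (1341 higher, 1128 lower), 4933 in CSF2 (2530 and 2403) and 888 in CSF3 (495 and 393). These counts depended on single libraries. The CSF1 count was 1536 without FBS vehicle 1, 1537 without CSF1 vehicle 1 and 1633 without CSF1 vehicle 2. That for CSF2 was 2959 without FBS vehicle 1, and that for CSF3 was 321, 346 and 1672 without FBS vehicle 1, 2 and 3, and 371 and 359 without CSF3 vehicle 2 and 3. In all 3 comparisons 142 genes were higher and 107 lower. Unchanged groups simulated together with the FBS vehicle libraries gave 0 of each, and independent lists would give 8.4 and 5.3. Because the FBS libraries were drawn as well, the values simulated here and below do not hold the deviations of the real ones. As 3 libraries cannot be split into parts of at least 2, part of the excess may come from the shared controls. The covariance of the log2 differences over genes was 0.144 for CSF1 and CSF2, 0.0609 for CSF1 and CSF3 and 0.0842 for CSF2 and CSF3, against 0.0288 in the simulation (highest 0.0316, 0.0309 and 0.0312). The correlation was 0.736, 0.453 and 0.513, against simulated means of 0.490, 0.502 and 0.487 (highest 0.526, 0.533 and 0.521). The covariance lay above the highest simulated value for all 3 pairs, and the correlation only for CSF1 and CSF2. The list test called 14, 17 and 11 lists in CSF1, CSF2 and CSF3, of which 5, 3 and 3 held with an estimated correlation.

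**Figure D4:**
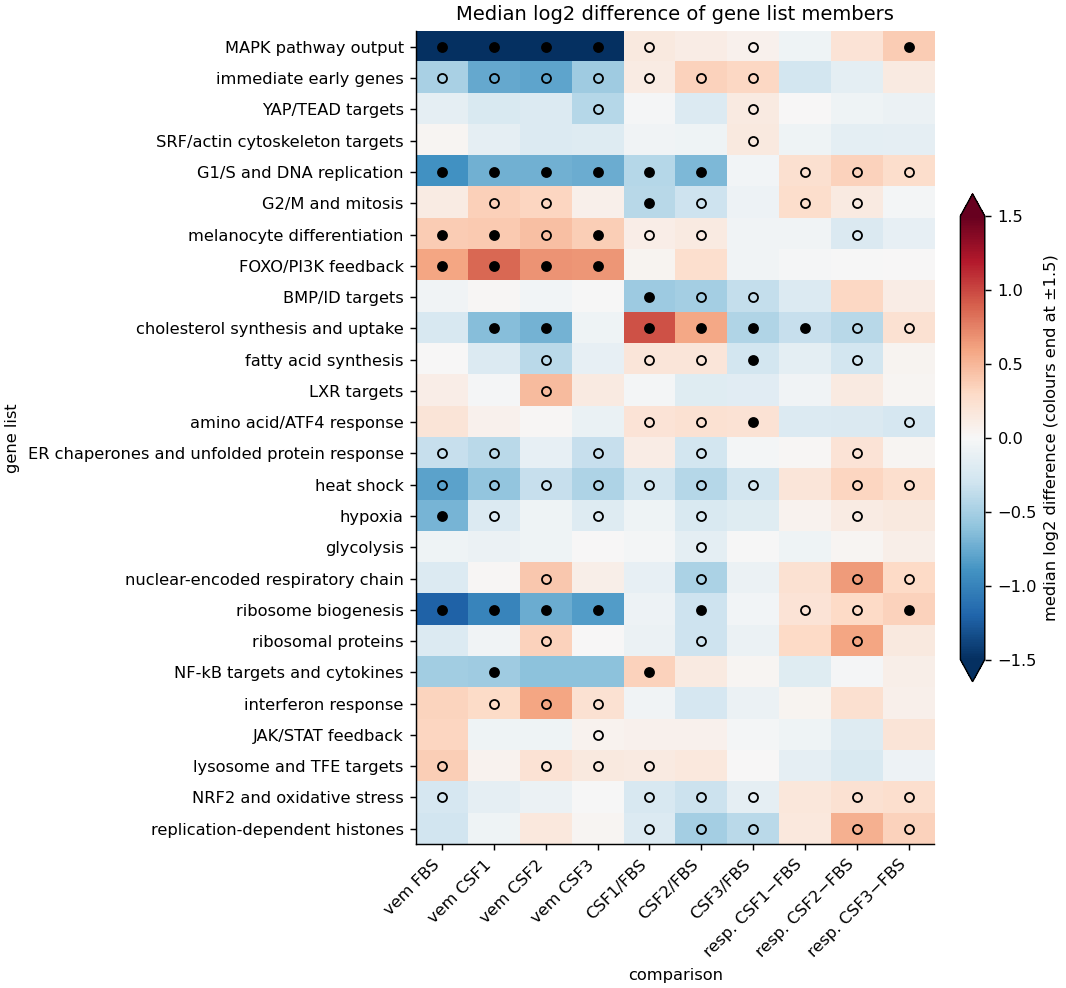
Median log2 difference over the tested members of each gene list (colour, ending at ±1.5) in 10 comparisons; filled circles mark lists called by camera with both the preset and an estimated correlation, and open circles lists called with the preset correlation only. The cholesterol list lay at 0.95 in CSF1, 0.58 in CSF2 and -0.45 in CSF3 against FBS under vehicle.

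The third question was whether the response to vemurafenib differed between CSF and FBS, tested as the difference of the log2 changes. In CSF3 the fall of the MAPK readouts was smaller. The difference was 2.42 ± 0.19 (SE) for DUSP6, 2.28 ± 0.13 for SPRY4, 1.43 ± 0.12 for ETV5, 1.39 ± 0.14 for MYC, 1.04 ± 0.10 for the phosphatase gene DUSP4 and 0.79 ± 0.13 for CCND1, with edgeR adjusted p from 5.24e-13 for SPRY4 to 0.000512 for CCND1. Under vemurafenib SPRY4 stood at 89.3 ± 5.02 CPM in CSF3 against 11.8 ± 0.823 in FBS, and MYC at 122 ± 5.93 against 51.1 ± 5.58. Of 19 MAPK list genes 9 had a smaller fall in CSF3 and none a larger one (11 and 0 adjusted over the list alone), with a median difference of 0.38, a camera adjusted p of 4.05e-17 and 7.12e-05 with an estimated correlation. EGR1 went the other way, with a difference of -2.40 ± 0.36 (adjusted p = 0.00111), and that of ETV4 was 0.21 ± 0.11 (adjusted p = 0.275).

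Other genes with a smaller fall in CSF3 were NFATC2, a calcium-regulated transcription factor (chromosome 20, 50003494 to 50179370; 1.81 ± 0.19), and ST8SIA1, a ganglioside sialyltransferase (1.69 ± 0.14). KCNJ2, a potassium channel gene, had a difference of 1.61 ± 0.29 (edgeR adjusted p = 0.00106). It stood at 4.26 ± 0.815 CPM under vehicle and 8.28 ± 1.37 under vemurafenib in CSF3, against 3.06 ± 0.205 and 1.91 ± 0.413 in FBS. FOXP3, a transcription factor, rose less in CSF3, with a difference of -1.56 ± 0.34. Ribosome biogenesis genes fell less in CSF3: 6 of 22 were called in that direction (8 adjusted over the list alone), with a median of 0.34, a camera adjusted p of 8.00e-06 and 0.0263 with an estimated correlation. With the estimate the call was lost without FBS vehicle 3, FBS vemurafenib 3 or CSF3 vehicle 1 (adjusted p up to 0.0823). Amino acid response genes had a lower response in CSF3, 5 of 20 (8 adjusted over the list alone), including NUPR1 at -1.22 ± 0.19 and SLC7A11, the cystine transporter, at -0.58 ± 0.11. That list had a camera adjusted p of 0.000242, which was lost (adjusted p = 0.139 with an estimated correlation).

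In CSF2 the responses of cholesterol genes were lower than in FBS. Of 23, 13 had a lower response and none a higher one (14 and 1 adjusted over the list alone), with a median of -0.42. The sterol oxidase gene MSMO1 differed by -1.53 ± 0.32. Nuclear-encoded respiratory chain genes (18 higher, 2 lower of 27, the same adjusted over the list alone, median 0.64), ribosomal protein genes (12 higher of 20, or 15 higher and 1 lower adjusted over the list alone, median 0.59) and replication-dependent histone genes (7 higher of 10, or 7 higher and 1 lower adjusted over the list alone, median 0.53) had higher responses. The camera adjusted p was 0.000136 for cholesterol, 3.52e-05 for the respiratory chain, 3.52e-05 for ribosomal proteins and 0.00455 for histones. None held (adjusted p = 0.139, 0.326, 0.326 and 0.326 with an estimated correlation). A correction for transcript length and GC ended the ribosomal protein call (adjusted p = 0.0889) and the histone call (adjusted p = 0.556), and reads of both families can be shared with paralogs or pseudogenes. Among MAPK readouts SPRY4 differed by 0.68 ± 0.13, CCND1 by 0.71 ± 0.13 and EGR1 by -1.85 ± 0.36, while DUSP6 at 0.48 ± 0.23 was not called (edgeR adjusted p = 0.133). MYC was called at 0.51 ± 0.14, but not without FBS vemurafenib 2 (adjusted p = 0.0526).

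In CSF1 few responses differed from those in FBS. The regulator of glycolysis PFKFB4 had a lower response, by -1.18 ± 0.21 (edgeR adjusted p = 0.00518), as had FDPS, an enzyme of the mevalonate pathway, by -0.60 ± 0.10 (adjusted p = 0.00242), while the zinc finger gene ZNF619 had a higher one, by 1.45 ± 0.22 (adjusted p = 0.00121). Cholesterol genes had a lower response: 3 of 23 were called, or 12 adjusted over the list alone, with a median of -0.34, a camera adjusted p of 2.12e-08 and 0.017 with an estimated correlation. With the estimate the call was lost without FBS vehicle 3, CSF1 vehicle 3 or CSF1 vemurafenib 3 (adjusted p up to 0.0799). Of 19 MAPK list genes 2 had a higher response and none a lower one (3 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.837). SPRY4 was called at 0.56 ± 0.13 (adjusted p = 0.0359), but not without FBS vehicle 1 or 2, FBS vemurafenib 1, 2 or 3, CSF1 vehicle 2 or CSF1 vemurafenib 1 or 3 (adjusted p up to 0.136). DUSP6 differed by 0.28 ± 0.24 (adjusted p = 0.579) and ETV5 by 0.03 ± 0.12 (adjusted p = 0.924) in the same test. Both estimates were far below the CSF3 differences of 2.42 for DUSP6 and 1.43 for ETV5. Their standard errors leave smaller differences in CSF1 open.

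The response difference was called for 123 genes in CSF1 (50 higher, 73 lower), 3378 in CSF2 (1754 and 1624) and 718 in CSF3 (323 and 395). With length and GC trends removed, the direction with more genes turned in CSF1 (136 higher, 89 lower) and CSF3 (332 and 260). It did not turn in CSF2 (1779 and 1360). Every library moved the CSF1 count by more than 1.5 times. It was 33, 33 and 411 without FBS vehicle 1, 2 and 3, 50, 56 and 43 without FBS vemurafenib 1, 2 and 3, 33, 41 and 553 without CSF1 vehicle 1, 2 and 3, and 25, 71 and 267 without CSF1 vemurafenib 1, 2 and 3. The CSF2 count was 1827 and 2007 without FBS vehicle 1 and 2, and 1845 and 2182 without CSF2 vemurafenib 2 and 3. The CSF3 count was 310, 246 and 1529 without FBS vehicle 1, 2 and 3, 267 and 269 without FBS vemurafenib 1 and 2, 228 and 434 without CSF3 vehicle 2 and 3, and 416 and 268 without CSF3 vemurafenib 2 and 3. These 3 comparisons share the FBS libraries. Of 32 lists 4, 13 and 9 were called in CSF1, CSF2 and CSF3, and 1, 0 and 2 held with an estimated correlation.

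**Figure D5:**
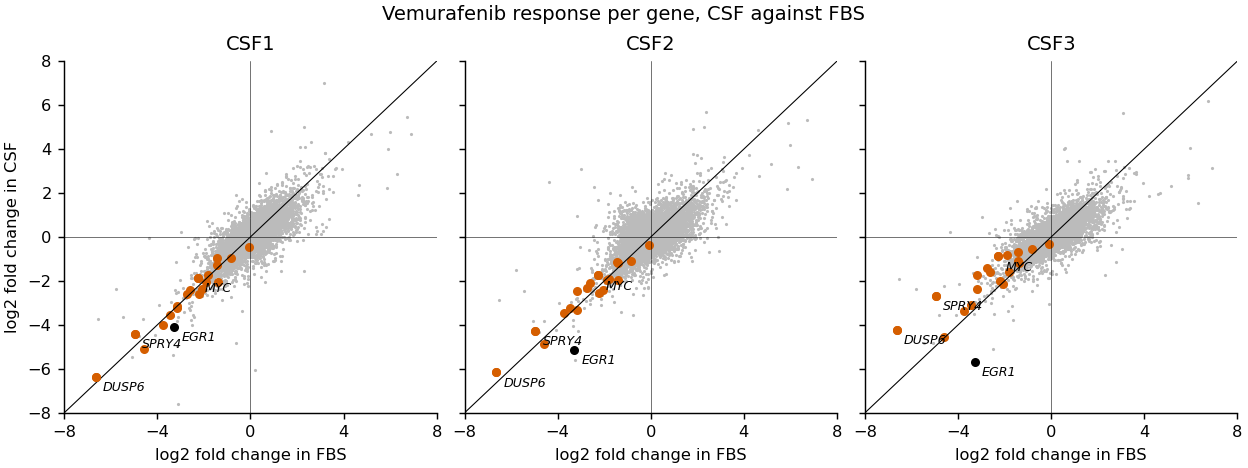
Log2 change under vemurafenib in each CSF (vertical axis) against that in FBS (horizontal axis), 1 point per tested gene, with MAPK pathway output genes in orange, EGR1 in black and equal change on the diagonal. DUSP6 lay at -6.65 in FBS and at -6.36, -6.16 and -4.22 in CSF1, CSF2 and CSF3.

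Over genes called in the same direction in the other CSFs, the mean response relative to FBS was 1.02 in CSF1 (3256 genes, jackknife SE 0.036), 0.827 in CSF2 (3559 genes, SE 0.036) and 0.790 in CSF3 (3835 genes, SE 0.022). This selection leaves out genes that responded in FBS only, so the values describe genes that responded in the other CSFs. Leaving out any of the 12 libraries gave 0.998 to 1.04 in CSF1, 0.810 to 0.850 in CSF2 and 0.781 to 0.807 in CSF3. Over the MAPK list alone, a choice made after the data had been seen, the values were 1.01, 0.961 and 0.718.

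The CSFs were also compared with one another under vehicle. Of 23 cholesterol genes 22 were higher in CSF1 than in CSF3 with none lower (23 adjusted over the list alone), with a median of 1.15, a camera adjusted p of 2.77e-38 and 2.64e-06 with an estimated correlation. Between CSF2 and CSF3 20 were higher (21 adjusted over the list alone), with a median of 0.97, 2.63e-27 and 2.76e-05. HMGCS1 was higher by 2.78 ± 0.12 in CSF1 and 2.43 ± 0.12 in CSF2 than in CSF3. MT1X was lower than in CSF3 by -4.39 ± 0.16 in CSF1 and -2.69 ± 0.14 in CSF2, with edgeR adjusted p of 2.97e-16 and 8.18e-13. TFRC was higher by 1.82 ± 0.09 in CSF1 than in CSF2. Fatty acid synthesis genes were higher than in CSF3 in CSF1 and in CSF2, 7 of 11 in each, also when adjusted over the list alone, with camera adjusted p of 8.94e-08 and 3.93e-08 and 0.00244 and 0.00178 with an estimated correlation. G1/S genes were lower than in CSF3, 13 of 22 in CSF1 and 19 in CSF2 (14 and 20 adjusted over the list alone), with camera adjusted p of 2.36e-10 and 3.31e-17, and 0.0181 and 0.00178 with an estimated correlation. Ribosome biogenesis genes were higher in CSF1 than in CSF2, 8 of 22 (15 adjusted over the list alone), with a camera adjusted p of 4.24e-09 and 0.00613 with an estimated correlation. The comparisons called 1298 genes between CSF1 and CSF2 (550 higher in CSF1), 2574 between CSF1 and CSF3 (1282 higher in CSF1) and 3266 between CSF2 and CSF3 (1729 higher in CSF2). That between CSF1 and CSF2 was 682 without CSF1 vehicle 2, 552 without CSF1 vehicle 3, 505 without CSF2 vehicle 1 and 702 without CSF2 vehicle 2.

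Under vemurafenib MAPK readouts were higher in CSF3 than in FBS, and some of them in CSF1 and CSF2. In CSF3 DUSP6 was higher by 3.57 ± 0.16 (log2, edgeR adjusted p = 1.31e-15), SPRY4 by 2.93 ± 0.10, ETV5 by 1.39 ± 0.09 and MYC by 1.26 ± 0.10. Of 19 MAPK list genes 16 were higher and none lower (17 adjusted over the list alone), with a median of 0.64, a camera adjusted p of 1.42e-25 and 5.65e-06 with an estimated correlation. SPRY4 was also higher than in FBS in CSF1 (19.6 ± 2.61 CPM, log2 difference 0.74 ± 0.10) and in CSF2 (27.8 ± 1.87 CPM, edgeR adjusted p = 1.30e-09), and MYC was higher by 0.55 ± 0.11 and 0.50 ± 0.11. DUSP6 was called at 0.84 ± 0.22 in CSF1, but not without FBS vemurafenib 1 or 2 or CSF1 vemurafenib 2 or 3 (edgeR adjusted p up to 0.213), and at 0.96 ± 0.21 in CSF2, but not without FBS vemurafenib 2 (0.0627). ETV5 was not called in CSF1 or CSF2 (-0.12 ± 0.09 and -0.02 ± 0.09, adjusted p = 0.521 and 0.919). The MAPK list, with 5 of 19 higher in CSF1 and none lower (5 and 1 adjusted over the list alone), had a camera adjusted p of 0.0277 there, lost without FBS vemurafenib 2 or CSF1 vemurafenib 3 (up to 0.213), after thinning to equal depth (0.0877) and with the estimate (adjusted p = 0.2 with an estimated correlation), and it was not called in CSF2 (camera adjusted p = 0.0773), where 4 were higher and none lower, also when adjusted over the list alone. EGR1 was lower in CSF3 by -1.80 ± 0.29 and in CSF2 by -1.65 ± 0.28. Of 23 cholesterol genes 12 were higher in CSF1 than in FBS with none lower (16 adjusted over the list alone), with a camera adjusted p of 1.65e-19 and 0.00019 with an estimated correlation. BMP target genes were lower in CSF1, 5 of 8 with 1 higher, also when adjusted over the list alone (camera adjusted p = 5.46e-08, adjusted p = 0.00158 with an estimated correlation), led by ID3 at -2.60 ± 0.19. MT1X differed by -2.85 ± 0.14 in CSF1, and TFRC by -2.30 ± 0.09 in CSF2. The comparisons called 559 genes in CSF1 (283 higher, 276 lower), 1839 in CSF2 (799 and 1040) and 1348 in CSF3 (669 and 679). The CSF1 count was 224, 210, 284 and 244 without FBS vemurafenib 1, FBS vemurafenib 2, CSF1 vemurafenib 1 and CSF1 vemurafenib 2. The CSF2 count was 998, 848, 869 and 989 without FBS vemurafenib 1, FBS vemurafenib 2, CSF2 vemurafenib 2 and CSF2 vemurafenib 3, and the CSF3 count was 808, 699 and 741 without FBS vemurafenib 1, FBS vemurafenib 2 and CSF3 vemurafenib 3.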

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

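The tests of transcript length and GC, here and for the lists, that of the FBS vehicle libraries, the division of the splits by equal numbers and the lowest share of untreated RNA were chosen only after the results were seen. What singled out the results in this part is a tested difference between the vemurafenib response in a CSF and that in FBS, in the edgeR model for genes and in camera for lists.

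In CSF1 the response differed for 123 genes, or 68 with every library thinned to equal depth. The largest differences upward were ZNF619 1.45, C11orf83 1.21, ADM 1.18, TTC5 1.17, TMA16 1.03 and ASF1A 1.02, and downward TMEM198 -1.53, PFKFB4 -1.18, WDR17 -1.15, ZNF341 -1.14, RIMS2 -1.06 and SYT11 -1.05 (log2), while SPRY4 differed by 0.56. Of these 13 genes only ZNF619, PFKFB4 and ZNF341 kept their call with each library left out. The numbers that lost it were 10 without FBS vehicle 1 (highest adjusted p of those lost 0.13), 7 without FBS vehicle 2 (0.129), 7 without FBS vemurafenib 1 (0.0967), 6 without FBS vemurafenib 2 (0.136) and 7 without FBS vemurafenib 3 (0.102). They were 8 without CSF1 vehicle 1 (0.155), 5 without CSF1 vehicle 2 (0.146), 9 without CSF1 vemurafenib 1 (0.139), 4 without CSF1 vemurafenib 2 (0.104) and 1, SPRY4, without CSF1 vemurafenib 3 (0.0721). The cholesterol list had a median difference of -0.34, the G1/S list 0.24, the G2/M list 0.26 and the ribosome biogenesis list 0.2, and the last 3 calls were lost with an estimated correlation (adjusted p = 0.393, 0.202 and 0.202). The cholesterol call held with it (adjusted p = 0.017), but not without FBS vehicle 3, CSF1 vehicle 3 or CSF1 vemurafenib 3 (up to 0.0799). Of 100 splits of the FBS and CSF1 libraries, drawn from 200 and keeping drug and group size, 15 gave at least as many genes, and the highest of the others was 2555, with all vemurafenib libraries exchanged between the media. Splits that exchange unequal numbers of vehicle and vemurafenib libraries, 59 of the others, carry the difference between the media into the response difference. In the 40 with equal numbers it cancels, but both media then stand in each group and widen its spread, so low counts there do not exclude chance. Of these 40, 2 gave as many genes in CSF1, which points to a structure of the samples, and 0 did in CSF2 or CSF3. The 2 gave 1105 genes with replicate 3 of all 4 groups exchanged and 361 with CSF1 vemurafenib 2 in place of 3. With the replicate block 76 genes were called, against 123 without it. The block fits 1 shift per replicate number, the same in all 8 groups. It cannot show shifts that differ between groups, so it does not decide whether replicate 3 stood apart. The splits therefore leave chance open for all 3 counts.

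In CSF2 the response differed for 3378 genes. The largest differences upward were RPS26P11 3.95, TIMM8B 2.65, RPSAP9 2.61, RPL39 2.55, CETN3 2.47 and TPRKB 2.46, and downward MUC20 -1.93, EGR1 -1.85, MSMO1 -1.53, PLEKHA7 -1.45, PKD1L1 -1.4 and SLC2A12 -1.36, while SPRY4 differed by 0.68, CCND1 by 0.71 and MYC by 0.51. RPS26P11 and RPSAP9 are ribosomal protein pseudogenes whose reads can come from the parent genes. The transcripts of the 6 upward genes had 348, 780, 888, 390, 2406 and 664 bases, against a median of 3314 over tested genes, and over all tested genes this response difference had a rank correlation of -0.3 with length. RPSAP9 lost its call without FBS vehicle 1 (adjusted p = 0.0857), FBS vehicle 2 (0.0848), FBS vemurafenib 2 (0.066), FBS vemurafenib 3 (0.0716), CSF2 vehicle 1 (0.0661), CSF2 vehicle 2 (0.0701), CSF2 vehicle 3 (0.0608), CSF2 vemurafenib 2 (0.0828) or CSF2 vemurafenib 3 (0.0752), and MYC without FBS vemurafenib 2 (0.0526). The 13 lists called had medians of 0.35 (G1/S), 0.13 (G2/M), -0.22 (melanocyte), -0.42 (cholesterol), -0.28 (fatty acid), 0.2 (ER chaperones), 0.32 (heat shock), 0.12 (hypoxia), 0.64 (respiratory chain), 0.3 (ribosome biogenesis), 0.59 (ribosomal proteins), 0.23 (NRF2) and 0.53 (histones). None held with an estimated correlation (adjusted p from 0.139 to 0.531). List calls were also lost with 1 library left out: G2/M without FBS vehicle 1 or 3, FBS vemurafenib 2, CSF2 vehicle 2 or 3 or CSF2 vemurafenib 3 (adjusted p up to 0.205) and after thinning (0.0825), and hypoxia without FBS vehicle 3, FBS vemurafenib 1 or 3, CSF2 vehicle 3 or CSF2 vemurafenib 1 or 3 (up to 0.0949) and after thinning (0.051). The ER chaperone call was lost without FBS vehicle 2 or CSF2 vemurafenib 2 or 3 (up to 0.0949), the melanocyte call without FBS vehicle 3 (0.0784) and the NRF2 call without FBS vehicle 1 (0.0645). Of 100 splits drawn from 200, 3 gave at least as many genes. The others were 3752, with all vemurafenib libraries exchanged, and 3398, with FBS vemurafenib 2 and CSF2 vemurafenib 1 exchanged.

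In CSF3 the response differed for 718 genes, or 436 with every library thinned to equal depth, of which 405 were among the 718. With length and GC trends removed 446 of the 718 were still called. Over all tested genes this response difference had a rank correlation of -0.26 with transcript length and 0.26 with GC. The largest differences upward were DUSP6 2.42, SPRY4 2.28, NFATC2 1.81, CCR1 1.73, ST8SIA1 1.69 and KCNJ2 1.61, and downward EGR1 -2.4, FOXP3 -1.56, DIO2 -1.51, IGSF10 -1.5, C8orf46 -1.43 and PLEKHA7 -1.43, while ETV5 differed by 1.43, CCND1 by 0.79 and MYC by 1.39. Calls were lost for 5 of these 15 genes without FBS vehicle 1 (highest adjusted p of those lost 0.153), 3 without FBS vehicle 2 (0.0728), 1 without FBS vehicle 3 (0.0603), 3 without FBS vemurafenib 1 (0.116) and 4 without FBS vemurafenib 2 (0.0978). The numbers were 2, 2 and 3 without CSF3 vehicle 1, 2 and 3 (0.12, 0.0899 and 0.0881), and 2, 3 and 4 without CSF3 vemurafenib 1, 2 and 3 (0.0791, 0.0877 and 0.152). The genes that lost calls were CCR1, DIO2, IGSF10, C8orf46 and PLEKHA7. CCR1 differed by 3.05 without FBS vemurafenib 2, and DIO2 by -0.99 without FBS vehicle 1. The lists called had medians of 0.38 (MAPK), 0.26 (G1/S), 0.23 (cholesterol), -0.25 (ATF4), 0.25 (heat shock), 0.3 (respiratory chain), 0.34 (ribosome biogenesis), 0.25 (NRF2) and 0.35 (histones), of which MAPK and ribosome biogenesis held with an estimated correlation, the latter not without FBS vehicle 3, FBS vemurafenib 3 or CSF3 vehicle 1 (adjusted p up to 0.0823). With 1 library left out, the cholesterol call was lost without FBS vehicle 2 or 3, CSF3 vehicle 2 or 3 or CSF3 vemurafenib 1 (adjusted p up to 0.104) and after thinning (0.0874), and the heat shock call without FBS vehicle 1, FBS vemurafenib 3, CSF3 vehicle 1 or 3 or CSF3 vemurafenib 3 (up to 0.109). The respiratory chain call was lost without FBS vehicle 1 or 2, FBS vemurafenib 3, CSF3 vehicle 2 or CSF3 vemurafenib 3 (up to 0.203), the histone call without FBS vehicle 1 or CSF3 vemurafenib 3 (up to 0.0908) and the NRF2 call without FBS vehicle 1 (0.059). Of 100 splits drawn from 200, 5 gave at least as many genes. The others were 1370, with all vemurafenib libraries exchanged, 1114, with FBS vehicle 3 and CSF3 vehicle 1 exchanged, and 774 and 736 with more vehicle libraries exchanged.

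The first pattern weighed is the large number of response differences in CSF2. With transcript length and GC trends removed 2475 of the 3378 genes were still called, and with every library thinned to 9304013 counts 2685 were, which argues against trend or depth as the whole cause. Length and GC may explain the ribosomal protein list, whose median went from 0.59 (SD over members 0.61) to 0.23 (SD 0.67) with 12 and then 8 members called higher, so that its call ended because the shift shrank. The design gives a biological explanation, the CSF itself, which was not tested apart from other properties of the medium.

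The second pattern is the smaller fall of MAPK genes in CSF3. Untreated RNA in the CSF3 vemurafenib libraries would have to make up a median of 21.3% to explain it, from 4.41% for DUSP6 to 42.7% for MYC over the 9 members called. By over 2 SE, 15 called genes lay below the level that the median share would leave, 2 of them (DUSP6 and SPRY4) among those members, which argues against such a share. At the lowest share 3 called genes lay below, and only EGR1, with 1.94% of its vehicle level, by over 2 SE. A share that low would not let EGR1 fall so far, but 1 gene picked from many does not decide it. That 8 of the 9 members needed more follows from taking the lowest need. Such a share would account in full for DUSP6 only. The list's median was 0.42 with length and GC trends removed and 0.4 after thinning, which argues against trends and depth. A CSF3 component that keeps part of the pathway active, or lowers the effective drug concentration, may be a cause, and these 2 were not tested apart. The opposite difference of EGR1 remains open.

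The third pattern is the cholesterol list, higher in CSF1 and CSF2 and lower in CSF3 than in FBS under vehicle. With length and GC trends removed the medians were 0.88, 0.54 and -0.4, and after thinning the CSF3 median, the one that kept the smallest share, was -0.4, which argues against trends and depth. The difference of 1.15 between CSF1 and CSF3 uses no FBS library, so FBS vehicle libraries out of line cannot explain that difference. It does not place FBS between these CSFs. How far each CSF lay from FBS, and the direction in CSF3, stay open to such libraries. Lipid supplied by each medium may be a cause, which was not tested.

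For the other comparisons each result has 10 splits of the libraries, which are too few for a share under 0.05, and 1 of 10, the real one, gave as many genes. The highest of the other splits was 0 for vemurafenib against vehicle in each medium (real 7313, 6055, 5657 and 4964). It was 2190 for CSF1 against FBS under vehicle (real 2469), with FBS vehicle 3 and CSF1 vehicle 3 exchanged, which points to a structure of the samples, 1 for CSF2 (real 4933) and 0 for CSF3 (real 888). On the second principal component these 2 libraries stood at -1.9 and -3.8, between FBS vehicle 1 and 2 at -31 and -25.5 and CSF1 vehicle 1 and 2 at 24.1 and 14.7. Their slopes on transcript length (log2 CPM per doubling) were -0.0081 and -0.0617, against -0.094 and -0.0747 for FBS vehicle 1 and 2 and 0.0072 and -0.0182 for CSF1 vehicle 1 and 2. Between CSFs it was 0, 1 and 0 (real 1298, 2574 and 3266), and under vemurafenib 0 for each CSF (real 559, 1839 and 1348).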

How the results depend on the processing

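The length and GC correction, alone or with the replicate block, and the relative size over MAPK genes only were chosen after the data had been seen. Of 809 pairs of named gene and comparison, 806 kept their direction and call with DESeq2 size factors and 806 with the DESeq2 Wald test. With no low-count filter 21 lost the call, with the replicate block 28, with the length and GC correction 32, with both 41, and with only the libraries compared 54. FASN in the CSF2 response difference went from -0.28 to 0.02 with the length and GC correction and to 0.02 with both. With 1 library left out 557 of 5568 tests lost the call and 0 reversed.

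With only the libraries compared the calls were 1215 (CSF1 against FBS, vehicle), 436 (CSF3, vehicle), 208 (CSF1, vemurafenib), 2579 (CSF3, vemurafenib), 13 (CSF1 response difference) and 1115 (CSF3 response difference). The CSF1 response difference had 319 calls with the DESeq2 Wald test, 76 with the block, 225 with the length and GC correction and 197 with both, and the CSF3 one had 473 with both. With the correction alone the direction with more calls turned in some comparisons, the CSF1 and CSF3 response differences among them. Against FBS under vehicle, higher and lower calls became 1332 and 1458 (CSF1), 2135 and 2608 (CSF2) and 509 and 538 (CSF3). They became 602 and 506 for CSF1 against CSF2, 1569 and 1983 for CSF2 against CSF3, and 797 and 629 for CSF3 under vemurafenib. With DESeq2 size factors CSF2 against FBS under vehicle turned too (2395 and 2515), among others. With an estimated correlation the lists called were 6, 7, 5 and 5 for vemurafenib in FBS, CSF1, CSF2 and CSF3, 5, 3 and 3 for each CSF against FBS under vehicle, 1, 0 and 2 for the response differences, 1 for CSF1 against CSF2, 5 for CSF2 against CSF3, and 2, 0 and 3 under vemurafenib. By fry, which tests whether the members of a list move 1 way and does not compare them with other genes, they were 29, 25, 28 and 25 for vemurafenib, 14 for CSF1 against CSF3 and 12 for CSF2 under vemurafenib. The length and GC correction left 5 lists in the CSF2 response difference. Rank correlations with transcript length were -0.33 for CSF1 against CSF2 and 0.3 for CSF2 against FBS, both under vehicle. There 828 of 1298 and 3906 of 4933 genes were still called with the correction. The relative size in CSF2 was 0.863 with genes selected at an adjusted p under 0.001 and 0.961 over MAPK genes, and in CSF3 0.718 over MAPK genes. The estimated correlation widens the null of each list test. For the other changes the cause was not tested.

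With 1 library left out the ranges were 1536 to 2916, 2959 to 5543 and 321 to 1672 for CSF1, CSF2 and CSF3 against FBS under vehicle, 25 to 553, 1827 to 4380 and 228 to 1529 for the response differences, 505 to 1544 for CSF1 against CSF2, and 210 to 674, 848 to 2018 and 699 to 1212 under vemurafenib. The list counts ranged from 4 to 10 in the CSF1 and from 5 to 11 in the CSF3 response difference. Replicate numbers gave no sign of a shift common to libraries of the same number: the mean residual correlation was -0.014 for the same number and 0.007 for different ones. Residuals cancel within a group, so the second value is no independent comparison. Pairs with the same number ranged from -0.4, for replicate 3 of CSF1 and FBS under vehicle, to 0.12. In 0 of 13 comparisons did every pair exceed 0.1. Thinning every library to 9304013 counts lowered the CSF1 response difference from 123 to 68 genes, that in CSF3 from 718 to 436 and vemurafenib in FBS from 7313 to 6507. It ended the list calls of hypoxia under vemurafenib in CSF3 (adjusted p = 0.0904), of SRF targets in CSF3 against FBS under vehicle (0.074), of glycolysis between CSF1 and CSF2 (0.0578), of MAPK (0.0877), receptor kinases (0.0532) and heat shock (0.0877) in CSF1 against FBS under vemurafenib, of G2/M (0.0825) and hypoxia (0.051) in the CSF2 response difference, and of cholesterol (0.0874) in that of CSF3.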

Other observations

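No test of a hypothesis is reported in this part, and the values below come from gene lists fixed at the outset. Markers of other cell types were looked up because CSF can carry cells. Erythroid markers summed to between 0.0681 and 0.441 CPM over the 8 groups. Summed leukocyte markers were 142 ± 17.9 CPM in FBS vehicle, where no CSF was present, and 158 ± 7.54, 152 ± 11.9 and 143 ± 19.2 CPM (SD, n = 3) in CSF1, CSF2 and CSF3 vehicle. Most of that sum was CD68, at up to 164 CPM, while PTPRC reached at most 0.149 CPM in any group. Neural and glial markers, several of which the line itself expressed, summed to 240 ± 23.0 CPM in FBS vehicle and 366 ± 15.0 CPM in FBS vemurafenib. Most of that sum was MBP, at 165 ± 17.1 and 289 ± 16.1 CPM, while GAD1 went from 49.6 ± 2.88 to 41.9 ± 0.863 CPM. Fibroblast and endothelial markers summed to a mean of 33.5 CPM in FBS vehicle and to between 31.1 and 32.0 CPM in the CSF vehicle groups, and under vemurafenib to 39.0 ± 1.27 CPM in FBS, 49.3 ± 8.96 in CSF1, 57.0 ± 11.3 in CSF2 and 52.0 ± 4.05 in CSF3. Most of that sum was LUM, at up to 48.9 CPM, while COL3A1 was at 0 and PECAM1 reached at most 0.136 CPM.

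Under vehicle the 8 metallothionein and zinc genes summed to 1072 ± 48.2 CPM in FBS, 451 ± 29.1 in CSF1, 861 ± 68.2 in CSF2 and 2623 ± 193 in CSF3. In CSF3 the sum under vemurafenib was 1727 ± 137 CPM. Reads can be shared between these paralogs in counting, to which a sum over the family is less open than a single member.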
